A study of Homo sapiens with 24 samples.

How the data were processed

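Total RNA was extracted with a column kit and poly(A) RNA was made into strand-specific libraries with the TruSeq stranded mRNA kit, per the labels' protocols. The cells were MCF7, grown in DMEM with serum and transfected with pools of siRNAs against ESR1, GATA3 or TET2 or with a non-targeting pool (siNT), per the labels. The siRNA sequences are not given in the sources used here. Reads were aligned to hg38/GRCh38 with STAR 2.6.1a and DESeq2 was also used by the authors, per the submitters' processing notes. The read counter, its strand setting and the annotation release are not given in the sources used here, so genes that overlap an antisense gene are uncertain, as are near-identical paralogs and pseudogenes.

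The authors deposited one table of RPKM values (reads per kilobase of transcript, scaled to library size), with 58036 genes and 24 libraries. Of these, 45 copies of pseudoautosomal genes on chromosome Y were left out, 37 of them with a value above 0, which left 57991 genes. Among them 53646 identifiers matched GENCODE release 29 with their version and 57387 without it, and symbols, types and coordinates were taken from that annotation of GRCh38. In 17188 genes the value was 0 in every library. No other column of per-sample values was present. Groups were taken from the titles. The numbers in the labels repeat within groups. Replicates were therefore numbered in the order of the samples, which coincides with 6 runs of the numeric codes in the titles that each hold 1 library of every group. The main model holds no block, and the title run as a block was an alternative.

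RPKM values are not counts, so no count test was used. The values of a gene in a library are whole multiples of what 1 read is worth, from which the depth was recovered, using multiples of up to 20. In M reads it was 31.1 to 38.2 in siNT (median 34.7), 30.2 to 42.8 in siESR1 (34.8), 27.4 to 38.6 in siGATA3 (35.6) and 30.4 to 39.4 in siTET2 libraries (33.7). With a tolerance of 0.05 read, 100% of the 3432 to 3735 values per library of single-exon genes were whole, and 74.5% to 76.7% over all matched genes, whose lengths in the table may differ from the annotation. Mitochondrially encoded genes took 2.00% to 2.71% of reads. Within every group, pairs of libraries differed by 5.26 to 13.0 times the sampling noise, over genes with at least 100 combined reads, so none was counted as a repeat of another.

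Values were analysed as log2(RPKM + 0.5) for the 18084 genes with a mean of at least 0.5 RPKM over the 24 libraries, 12124 of them protein-coding. A fold change is on this scale, which understates the change of low genes, unless a ratio of mean RPKM is given. One model with 4 groups was fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean, and the 3 knockdowns were compared with siNT and with each other. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and a gene was said to rise or fall at an adjusted p under 0.05. Genes with an absolute log2 fold change of at least 1 were counted in addition. The targeted genes were also compared by a two-sided exact permutation test of mean RPKM over all regroupings of 6 and 6 libraries. On simulated data with known changes the limma step recovered 50%, 30% and 36% of genes changed by 1.2-fold in siESR1, siGATA3 and siTET2 contrasts, 86%, 84% and 90% at 1.5-fold and 98%, 100% and 100% at 2-fold. Unchanged genes made up 7.22%, 1.89% and 5.78% of the calls. All 3 simulations used the same siNT means and spreads, so their percentages differ only by the random draw. Far fewer genes were changed in them than were called in the data, which makes the adjusted threshold stricter than in the data.

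Before the data were examined, 21 gene lists were fixed: estrogen-induced genes, estrogen-repressed genes, luminal identity, basal and mesenchymal markers, mitosis, DNA replication and S phase, p53 targets, the BCL2 family, interferon response, DNA methylation machinery, ER cofactors and chromatin partners, the unfolded protein response, cholesterol synthesis, hypoxia and glycolysis, NF-kB targets, YAP/TEAD and TGF-beta targets, growth factor receptors and ligands, stromal, endothelial and immune markers, mitochondrially encoded genes, oxidative phosphorylation, and ribosomal proteins. Each was tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Where a count adjusted over the list alone is not printed, it was equal to the count over all genes tested.

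Named genes follow a rule fixed at the same time. It took the 10 largest rises and 10 largest falls of each knockdown among protein-coding genes past the threshold with a mean of at least 1 RPKM and no overlap between the 6 knockdown and 6 siNT values. It also took 6 per direction for each direct contrast, 8 per direction for genes shared between knockdowns, and members of the fixed lists. Overlaps were set beside those of independent lists, of 20 simulations of unchanged groups that share the siNT libraries, of all 20 splits of the siNT libraries into 3 and 3 and, for all 3 knockdowns, of all 90 assignments of 2 siNT libraries to each, the last of these added after the data were seen.

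The 3′ UTRs of 11919 protein-coding genes were searched for heptamers whose carriers had lower fold changes than other genes, leaving out the genes that fell at least 2-fold, with 100 permutations of the fold changes. The 4 heptamers with the lowest z were kept for each knockdown, passing over any that was an earlier pick shifted along the sequence. Variants that differ from an earlier pick at a single base were not passed over. CCCTACT, ACCTACT and TCCTACT of siESR1, GACCAGA and GACCAGC of siGATA3, and GAGGGTA, GAGGGTT and TAGGGTA of siTET2 therefore do not count as separate motifs. In 5 of 5 simulated data sets the planted heptamer ranked first. The planted shift was larger than the differences in median between carriers and other genes for the siGATA3 and siTET2 heptamers. These simulations therefore do not show that shifts of that size are found. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used beside R.

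The alternatives tried were other pseudocounts (0.1 and 1), other filters, median-of-ratios scaling, quantile normalization, rescaling to a fixed total, fits of the compared groups alone, array weights, no mean-variance trend, replicate blocks, averaging of libraries that share a label number, and leaving out each library in turn. Separate fits of the earlier and later title runs, protein-coding genes alone, correction for GC content and length, and leaving out heptamer carriers were added after the data were seen.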

Results

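RNA was sequenced from MCF7 cells, an established human breast cancer cell line that expresses the estrogen receptor ER, the product of ESR1, and grows in response to estrogen. The cells had been transfected with siRNA pools directed at ESR1, GATA3 or TET2, or with a non-targeting pool (siNT). Each of the 4 groups held 6 libraries, 24 in all. GATA3 is a transcription factor of luminal breast cells, and TET2 is an enzyme that oxidises methylated cytosine in DNA. The expression values held between 27.4 M and 42.8 M counted reads per library (M, the SI prefix mega), and 15411 to 16061 genes per library lay above 1 RPKM. At these depths 1 read on a transcript of 1 kb was worth 0.0233 to 0.0365 RPKM. The labels do not say that the 6 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The coordinates below are those of GRCh38.

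The level of each targeted gene was examined first, in every group. ESR1 (ENSG00000091831, chromosome 6) fell from 1817 ± 104 RPKM in siNT libraries (mean ± SD, n = 6) to 197 ± 19.5 RPKM in siESR1 libraries, which was 9.22-fold lower. GATA3 (ENSG00000107485, chromosome 10, 8045378 to 8075203) fell from 1741 ± 46.7 RPKM to 334.9 ± 25 RPKM in siGATA3 libraries, 5.20-fold lower. TET2 (ENSG00000168769, chromosome 4, 105145875 to 105279816) had a far lower baseline, 14.9 ± 1.64 RPKM, and fell to 4.86 ± 0.51 RPKM in siTET2 libraries, 3.06-fold lower. In each case the 6 knockdown libraries lay below all 6 siNT libraries (two-sided exact permutation test, p = 0.00216, the smallest that 6 against 6 libraries can give). TET2 was also lower in the other knockdowns, at 3.22 ± 0.57 RPKM in siESR1 libraries (4.61-fold lower than siNT) and 6.31 ± 0.74 RPKM in siGATA3 libraries (2.35-fold lower). Its level in siESR1 libraries was below that in siTET2 libraries (log2 difference siTET2 minus siESR1 of 0.53, standard error 0.09, limma adjusted p = 1.62e-05). ESR1 was 1.15-fold lower in siTET2 libraries (1574 ± 86.3 RPKM, limma adjusted p = 0.0101) and rose in siGATA3 libraries (2184 ± 182 RPKM, log2 fold change 0.26), a call that was lost after quantile normalization. GATA3 fell by 0.26 on the log2 scale in siESR1 libraries and differed from siNT by -0.07 in siTET2 libraries, which did not pass (limma adjusted p = 0.263).

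**Figure D1:**
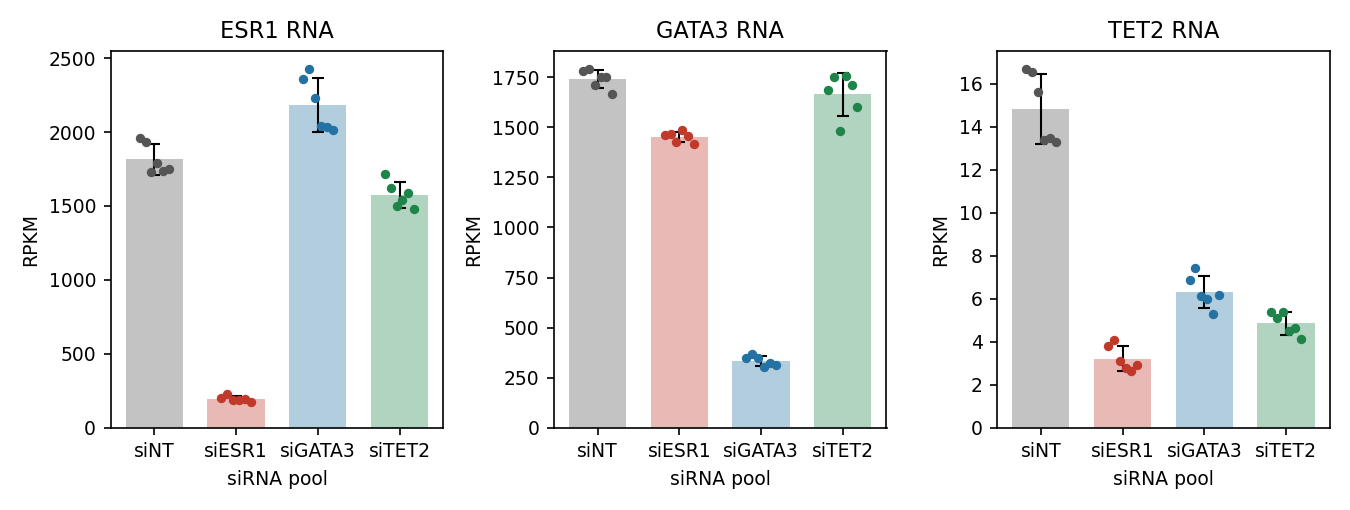
RPKM of ESR1, GATA3 and TET2 on linear axes in the 4 groups of libraries; points are the 6 libraries of a group, bars their mean and error bars 1 SD. Each targeted gene is lowest in the libraries of its own siRNA pool except TET2, whose mean is 3.22 RPKM in siESR1 libraries and 4.86 RPKM in siTET2 libraries.

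Knockdown of ESR1 against siNT asks which transcripts depend on the receptor in these cells. Genes that estrogen is known to induce collapsed. GREB1, a receptor cofactor and an early estrogen target (chromosome 2, 11482341 to 11642788), fell from 619.2 ± 65.7 to 22.3 ± 2.62 RPKM (n = 6 each), and AREG, an EGF receptor ligand (chromosome 4, 74445134 to 74455009), fell from 88.5 ± 15.8 to 3.23 ± 1.03 RPKM. TFF1, a secreted trefoil peptide, was 18.2-fold lower, and AGR3, a protein disulfide isomerase relative, went from 14.6 ± 2.49 to 0.16 ± 0.04 RPKM. PGR, which encodes the progesterone receptor, fell by 2.77 and MYB by 3.06 on the log2 scale. Of the 35 estrogen-induced genes fixed beforehand, 31 fell and 4 rose, with a median log2 fold change of -1.49 (camera adjusted p = 6.46e-10, and 0.0119 with an estimated correlation). Among the 4 that rose was CCND1, which encodes cyclin D1 (log2 fold change 0.90), together with SUSD3 (1.06). In the opposite direction, 10 of 12 estrogen-repressed genes rose and 1 fell, with a median of 0.93 (camera adjusted p = 6.6e-05, and 0.0119 with an estimated correlation), led by the surface antigen gene PSCA (2.99) and the stress-response gene TP53INP1 (1.92).

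Other genes rose steeply after ESR1 knockdown. ACHE, which encodes acetylcholinesterase (chromosome 7, 100889994 to 100896974), went from 1.30 ± 0.27 to 48.5 ± 4.25 RPKM, and CHRD, which encodes the BMP antagonist chordin (chromosome 3, 184380073 to 184390736), from 3.60 ± 0.53 to 71.2 ± 9.22 RPKM. S100A4 was 21.3-fold higher, S100A9, a calgranulin, rose from 3.24 ± 0.37 to 44.9 ± 3.81 RPKM, and the retinaldehyde dehydrogenase gene ALDH1A3 rose from 38.3 ± 11.8 to 471.4 ± 55.9 RPKM. VAT1L, TNFAIP2, DIO3, GPR78 and CAPN5 completed the 10 largest rises. Besides those above, the 10 largest falls held TMEM64 (-4.35), PKIB (-4.12), SLC4A10 (-3.98), the GDNF receptor gene GFRA1 (-3.94), the amino acid transporter gene SLC6A14 (-3.76) and the neural transcription factor gene ASCL1 (-3.58).

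Several other groups of genes moved in siESR1 libraries. Of 25 mitosis genes 19 fell and 2 rose, with a median of -0.49 (camera adjusted p = 0.00127). FOXM1, a transcription factor of mitotic genes, fell by 1.79 and AURKA by 0.98, whereas TOP2A rose by 0.40. The 30 DNA replication genes divided, 9 rising and 10 falling, with a median of 0.05 and a mean of -0.06 (camera adjusted p = 0.661; 8 and 10 adjusted over the list alone). In that list CCNE1 rose (1.06), as did TYMS (0.61), and GINS1 fell by 2.48. Among 22 p53 targets 15 rose and 3 fell, with a median of 0.68 (camera adjusted p = 7.86e-04), including CDKN1A, the cell cycle inhibitor p21 (1.32), and BBC3 (1.12). NF-kB targets rose in 9 of 10 cases with a median of 0.85 (camera adjusted p = 5.73e-04), including TNFAIP3 (1.65). BCL2 family genes rose in 6 and fell in 3 of 9 cases (camera adjusted p = 0.0401). This call was lost with median-of-ratios scaling (adjusted p = 0.073), quantile normalization (0.0944), no filter on low values (0.113), a mean of at least 2 RPKM (0.0528) and the title run as a block (0.0527). The 6 included BAK1 and BAD, which promote apoptosis (1.57 and 1.13), and among the 3 was PMAIP1, which also does (-1.08). Cholesterol synthesis genes fell in 14 and rose in 7 of 24 cases, with a median of -0.46 (camera adjusted p = 0.0392), SREBF2, their transcriptional regulator, falling by 1.96. That call was lost with the title run as a block (adjusted p = 0.0527). The 17 members without any of the 4 heptamers whose carriers fell most in siESR1 libraries had a median of -0.075, with 8 falling and 6 rising, and the 7 with one had a median of -1.30. Ribosomal protein genes fell in 27 of 30 cases (27, and 1 rose, adjusted over the list alone) with a median of -0.30 (camera adjusted p = 7.27e-06), RPLP1 by 1.39. With an estimated correlation the adjusted p was 0.598 for mitosis, 0.302 for p53 targets, NF-kB targets and cholesterol synthesis, 0.142 for the BCL2 family and 0.454 for ribosomal proteins, so that only the estrogen-induced and estrogen-repressed lists kept their calls.

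Across the transcriptome, 13075 of 18084 tested genes passed an adjusted p of 0.05 in limma (5429 rose and 7646 fell, but 6606 and 6365 after quantile normalization and 6411 and 6632 with median-of-ratios scaling), and 2083 of them changed at least 2-fold (703 up and 1380 down). The called genes changed by a median of 1.40-fold. Of the 1005 other protein-coding genes searched that fell at least 2-fold, 52.3% carried one of the siESR1 heptamers in the 3′ UTR, against 32.5% of the rest. Principal component 4, with 2.46% of the variance, parted the libraries into earlier and later title codes, with 3 libraries of every group on each side. The gap was narrow and not at 0, from 1.9 in siTET2 replicate 2 to 2.76 in siNT replicate 6. Within the earlier and the later libraries the counts were 11303 and 11513, and 9925 genes passed in both in the same direction and 5 in opposite directions.

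**Figure D2:**
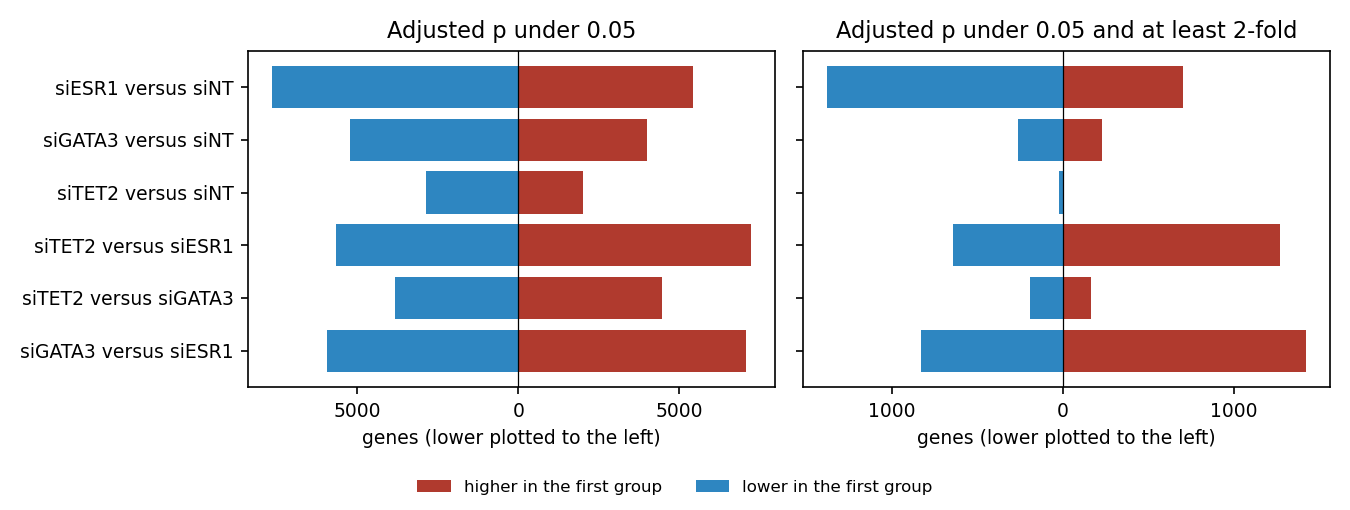
Number of genes past an adjusted p of 0.05 (left) and past it with at least a 2-fold change (right) in the 6 contrasts, higher in the first-named group to the right of 0 and lower to the left. Against siNT the totals are 13075 for siESR1, 9229 for siGATA3 and 4892 for siTET2, and 2083, 488 and 32 at 2-fold or more.

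Knockdown of GATA3 against siNT addresses the genes that depend on this luminal transcription factor. Genes of mitosis and DNA replication fell. All 25 mitosis genes fell, with a median log2 fold change of -0.90 (camera adjusted p = 2.36e-19, and 0.0767 with an estimated correlation), including CDC20 (-1.30) and the proliferation marker gene MKI67 (-1.02). Of 30 DNA replication genes 29 fell, with a median of -0.99 (camera adjusted p = 1.13e-20, and 0.0851 with an estimated correlation), including ORC1 (-1.56) and MCM10 (-1.44), which act at replication origins. CCND1 fell by 1.09. In the methylation machinery list 12 of 19 genes fell and 2 rose (camera adjusted p = 0.0223, 0.184 with an estimated correlation, and 0.0551 among genes with a mean of at least 2 RPKM). These included UHRF1 (-1.10), HELLS (-1.06) and the maintenance methyltransferase gene DNMT1 (-0.50).

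The largest fall after GATA3 knockdown was in STC1, which encodes the hormone stanniocalcin (chromosome 8, 23841915 to 23854807), from 11.8 ± 1.54 to 0.74 ± 0.13 RPKM. ADAMTS19, a secreted protease gene (chromosome 5, 129460265 to 129738683), fell from 11.6 ± 1.41 to 1.54 ± 0.41 RPKM. PDZK1 (-2.26), PPP1R3C (-2.19), COL4A5 (-2.18), IGFBP3 (-2.17), BANK1 (-2.16), GLA (-2.08) and ANP32E (-2.05) followed. The largest rise was in MAP1B, a microtubule-associated protein gene (chromosome 5, 72107234 to 72209570), from 15.9 ± 2 to 134.9 ± 24.8 RPKM. TMPRSS11E (chromosome 4, 68447449 to 68497604) went from 0.24 ± 0.14 to 4.85 ± 0.93 RPKM. The mesenchymal filament gene VIM reached 6.25 ± 1.22 RPKM from 0.70 ± 0.30 RPKM, and GABRP (2.66), C15orf48 (2.64), TMCC3 (2.42), KLF2 (2.37) and CDC14A (2.20) also rose. UGT2B17 (2.64) and UGT2B15 (2.44) encode near-identical androgen-conjugating enzymes between which reads can be misassigned, so their separate values are uncertain.

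Estrogen-induced genes showed no common direction by camera in siGATA3 libraries, with 16 falling and 11 rising among 35 and a median of -0.05 (camera adjusted p = 0.717, and 16 fell and 12 rose adjusted over the list alone). Fry, which does not compare a list with other genes, called this list downward (adjusted p = 2.16e-05). TFF1 and PGR rose (0.50 and 1.01), while PDZK1 fell by 2.26 and STC2 by 1.98. Estrogen-repressed genes rose in 9 and fell in 3 of 12 cases, with a median of 0.53 (camera adjusted p = 5.61e-04, and 0.0668 with an estimated correlation). Hypoxia and glycolysis genes rose in 20 and fell in 2 of 25 cases, with a median of 0.38 (camera adjusted p = 2.87e-06, and 0.184 with an estimated correlation), including NDRG1 (1.29) and HK2 (0.95). NF-kB targets rose in 9 of 10 cases, with a median of 0.64 (camera adjusted p = 4.28e-05, and 0.184 with an estimated correlation), including BIRC3 (1.49) and RELB (1.44). Cholesterol synthesis genes rose in 12 and fell in 4 of 24 cases, with a median of 0.15 (camera adjusted p = 0.0123, and 0.184 with an estimated correlation). In all, 9229 genes passed in limma, 3996 rising and 5233 falling, with a median fold of 1.27 among the called genes, and 488 changed at least 2-fold (228 up and 260 down). The split depended on scaling, with 4741 rising and 4638 falling after quantile normalization. Within the earlier and the later libraries 7410 and 7010 genes passed, 5694 of them in both in the same direction and 0 in opposite directions.

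Knockdown of TET2 against siNT bears on the role in ER-regulated expression that the series title gives to this enzyme. The changes were many and small. Of 4892 genes past the threshold in limma, 2019 rose and 2873 fell, with a median fold of 1.18, and 32 changed at least 2-fold, 9 up and 23 down. After quantile normalization 2488 rose and 2458 fell, and with RPKM rescaled to a common total 1771 rose and 3291 fell. Within the earlier and the later libraries alone 2504 and 2513 genes passed, 1417 of them in both in the same direction and 0 in opposite directions, with a correlation of 0.55 between the fold changes across genes, which are not independent replicates. In simulated data the test recovered 36% of genes changed by 1.2-fold, 90% at 1.5-fold and 100% at 2-fold. Far fewer genes were changed there than were called here, and the spreads simulated were not particular to this contrast.

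The estrogen-induced list as a whole fell in siTET2 libraries and the estrogen-repressed list rose, with smaller medians than after ESR1 knockdown. Of 35 estrogen-induced genes 18 fell and 1 rose (21 and 1 adjusted over the list alone), with a median of -0.20 (camera adjusted p = 1.52e-05, and 0.0613 with an estimated correlation). RAB31, a small GTPase gene, fell by 0.95, the transcription factor gene EGR3 by 0.67, the chemokine gene CXCL12 by 0.60 and PGR by 0.56, and all 4 fell in siESR1 libraries too. SUSD3 fell by 1.11 and CCND1 by 0.37, although both rose in siESR1 libraries, and the 3′ UTR of SUSD3 carried GAGGGTA, one of the siTET2 heptamers described below. The 3 members that fell most with ESR1 knockdown did not pass: GREB1 was at 551.3 ± 64.3 RPKM against 619.2 ± 65.7 in siNT (limma adjusted p = 0.187), and AREG and TFF1 differed from siNT by -0.29 and 0.12 on the log2 scale (limma adjusted p = 0.171 and 0.234). Of 12 estrogen-repressed genes 7 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 7.92e-05, and 0.0286 with an estimated correlation), including PSCA (0.94) and BCAS1 (0.48). The 8 of them without any siTET2 heptamer had a median of 0.17, with 3 rising and 1 falling. In the estrogen-induced list 10 of the 14 carriers fell, and 8 of the 21 others, which had a median of -0.20.

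Proliferation genes also fell in siTET2 libraries. All 25 mitosis genes fell, with a median of -0.32 (camera adjusted p = 1.81e-15, and 0.0613 with an estimated correlation), led by AURKA (-0.46) and HMMR (-0.46). DNA replication genes fell in 24 and rose in 2 of 30 cases (26 and 3 adjusted over the list alone), with a median of -0.26 (camera adjusted p = 5.84e-10, and 0.227 with an estimated correlation). MCM10 (-0.90) and the thymidylate synthase gene TYMS (-0.81) led the falls, and CCNE1 and CCNE2 were the 2 that rose, calls that were both lost with no filter on low values. In the methylation machinery list 7 of 19 genes fell and 1 rose (9 and 1 adjusted over the list alone), with a median of -0.10 (camera adjusted p = 0.0264, 0.196 with an estimated correlation, 0.0636 after quantile normalization and 0.0757 among genes with a mean of at least 2 RPKM). UHRF1, which recruits DNMT1 to replicated DNA, fell by 0.84, and OGT, a partner of TET enzymes, rose by 0.36. The 8 members without a heptamer had a median of -0.06, with 3 falling. Of the TET2 relatives, TET1 fell by 0.23 from a mean of 0.91 RPKM, and TET3 differed from siNT by 0.01 (limma adjusted p = 0.929).

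Cholesterol synthesis genes fell in 14 of 24 cases and none rose (15 and 1 adjusted over the list alone), with a median of -0.14 (camera adjusted p = 1.92e-05, and 0.0408 with an estimated correlation). DHCR24, the last reductase of the pathway, fell by 0.63 and the LDL receptor gene LDLR by 0.36. YAP/TEAD and TGF-beta targets rose in 7 and fell in 1 of 18 cases (9 and 1 adjusted over the list alone), with a median of 0.18 (camera adjusted p = 0.00373, and 0.0613 with an estimated correlation), including TGFBI (0.68). Ribosomal protein genes rose in 14 and fell in 1 of 30 cases (16 and 1 adjusted over the list alone), with a median of 0.09 (camera adjusted p = 8.91e-07, and 0.389 with an estimated correlation). Reads of this family can be shared with its many processed pseudogenes. Mitochondrially encoded genes had a median of 0.08 with 1 of 13 past the threshold, MT-CO2 (lost after quantile normalization, with rescaled RPKM and with no filter on low values), and 0 adjusted over the list alone (camera adjusted p = 0.0399, and 0.691 with an estimated correlation). That median was -0.039 after quantile normalization, so it has no firm direction, and the call was lost with rescaled RPKM (adjusted p = 0.0544), with fry (0.239) and among genes with a mean of at least 2 RPKM (0.0504).

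The largest rises in siTET2 libraries were in ANO7, an anoctamin gene (chromosome 2, 241188509 to 241225377), from 7.11 ± 0.89 to 16.2 ± 2.41 RPKM, and in the kinase gene PSKH1 (chromosome 16, 67893272 to 67929678), from 13.8 ± 1.77 to 29 ± 0.99 RPKM. ANKRD33B (1.04), PSCA (0.94), DYRK1B (0.93), YPEL2 (0.93), LY6H (0.89), COL4A2 (0.88), PLA2G10 (0.88) and CTDSP2 (0.86) followed. The largest falls exceeded that of TET2 itself (-1.52) in 3 protein-coding genes. LAMTOR1, which encodes a lysosomal anchor of mTORC1 signaling (chromosome 11, 72085895 to 72103387), went from 106.9 ± 5.1 to 28.4 ± 3.07 RPKM. SPTSSB, a serine palmitoyltransferase subunit gene (chromosome 3, 161344792 to 161372880), went from 176.8 ± 7.27 to 56.5 ± 3.22 RPKM, and the corepressor gene AES fell by 1.57. ANO6 (-1.42), FCF1 (-1.33), CCDC25 (-1.28), TMEM64 (-1.20), RPN2 (-1.18) and PXYLP1 (-1.12) made up the rest. Of the protein-coding genes other than TET2 that fell at least 2-fold, all 16 carried in the 3′ UTR at least 1 of the 4 heptamers whose carriers, among the other genes, had the lowest fold changes, against 33.9% of those other genes. The 3′ UTR of ESR1 carried 2 of these heptamers, and that of GATA3 also 2.

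**Figure D3:**
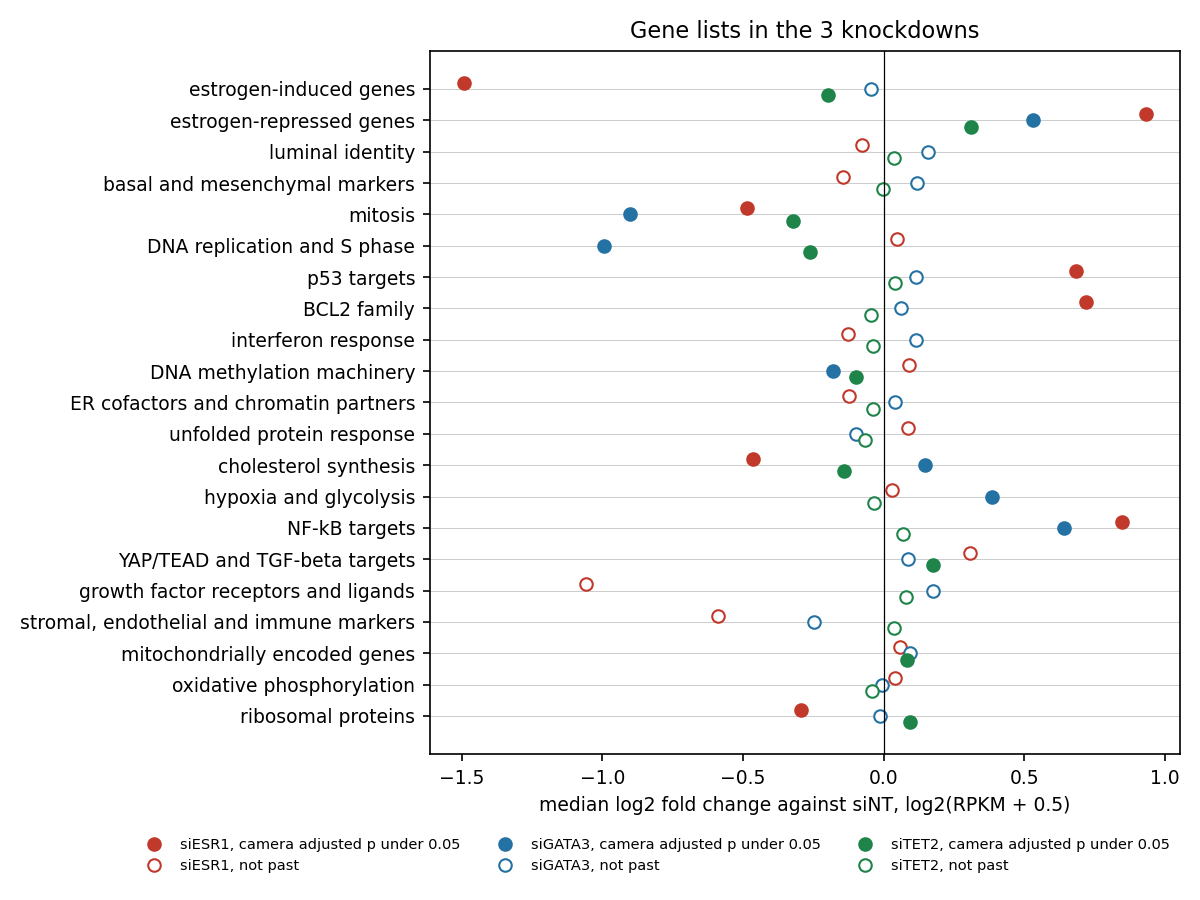
Median log2 fold change against siNT, on the log2(RPKM + 0.5) scale, of the tested members of 21 gene lists in siESR1, siGATA3 and siTET2 libraries; filled points passed a camera adjusted p of 0.05 and open points did not. Estrogen-induced genes have medians of -1.49, -0.05 and -0.20, and mitosis genes of -0.49, -0.90 and -0.32, in that order.

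The knockdowns were then compared with each other directly. Between siTET2 and siESR1 libraries 12898 genes passed in limma, 7236 higher and 5662 lower in siTET2 (6181 and 6740 after quantile normalization), and 1912 differed at least 2-fold. Estrogen-induced genes were higher in siTET2 in 31 and lower in 3 of 35 cases, with a median log2 difference of 1.32 (camera adjusted p = 5.51e-09, and 0.0365 with an estimated correlation). GREB1, AGR3, AREG, TFF1, MSMB and PKIB led that side, and ACHE, S100A9, CHRD, ALDH1A3, S100A4 and DIO3 the other. DNA replication genes were lower in siTET2 than in siESR1 in 21 and higher in 5 of 30 cases, with a median of -0.31 (camera adjusted p = 0.00423, and 0.694 with an estimated correlation). Between siTET2 and siGATA3 libraries 8294 genes passed, 4479 higher and 3815 lower in siTET2, and 356 differed at least 2-fold. All 25 mitosis and all 30 replication genes were higher in siTET2, with medians of 0.56 and 0.67 (camera adjusted p = 6.12e-15 and 3.66e-19, and both 0.117 with an estimated correlation). Cholesterol synthesis genes were lower in siTET2 than in siGATA3 in 16 and higher in 2 of 24 cases (17 and 2 adjusted over the list alone), with a median of -0.31 (camera adjusted p = 1.02e-07, and 0.0147 with an estimated correlation). Between siGATA3 and siESR1 libraries 13030 genes passed, 7086 higher and 5944 lower in siGATA3 (6286 and 6742 after quantile normalization), and 2246 differed at least 2-fold. ASCL1 was among the 6 largest differences, since it fell by 3.58 with ESR1 knockdown and rose by 1.84 with GATA3 knockdown. SULF1 likewise fell by 3.43 and rose by 1.27. Within the earlier and the later libraries the counts of these 3 contrasts were 11203 and 11346, 6557 and 5774, and 11484 and 11529.

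Genes that changed in more than 1 knockdown were counted by direction. Independent lists ignore that some genes pass more readily in every contrast, so they can understate the overlap to be expected. Between siGATA3 and siTET2, 2964 genes passed in the same direction and 514 in opposite directions (1164 rose in both where independent lists would give 446, and 1800 fell where they would give 831). Both groups carry the same label numbers, which apart from number 1 no siNT library carries. A difference tied to these numbers could add to this overlap. ANO7, DYRK1B, YPEL2, the proliferation antagonist gene MXD4 (1.18 and 0.82) and COL4A2 rose in both, and DGKG, PXYLP1, CDH26, MCM10, UHRF1, TYMS and PCP4 fell in both. Between siESR1 and siTET2, 2687 genes passed in the same direction and 1378 in opposite directions (1035 rose where independent lists would give 606, and 1652 fell where they would give 1215). PSCA, PLA2G10 and BTG2 rose in both, and FCF1, TMEM64, NUCKS1, RAB31 and FOXN3 fell in both. Between siESR1 and siGATA3, 4654 genes passed in the same direction and 2774 in opposite directions (1830 rose where independent lists would give 1200, and 2824 fell where they would give 2213). SEMA7A, GDF15 and RND1 rose in both, and STC1, PDZK1, COL4A5, BANK1 and ANP32E fell in both. In all 3 knockdowns 663 genes rose and 1114 fell, where independent lists would give 134 and 351.5. Simulated unchanged groups gave 0 and 0, but such groups yield almost no calls, so this does not measure what shared controls add. With the siNT libraries split into 2, 2 and 2 the counts were 263 and 451.5 in the median of 90 assignments, where independent lists would give 39.9 and 116.3. All parts come from the same siNT pool, so an effect of that pool itself would still appear as a change shared by the knockdowns. ANKRD33B, LY6H, PSKH1 and YPEL2 led the shared rises, and TET2, CDH26, DUSP7 and ITGA2B the shared falls. Of the falls named in this comparison, DGKG, PXYLP1, FCF1, TMEM64 and DUSP7 fell at least 2-fold in siTET2 libraries and carried a siTET2 heptamer. A seed effect of the TET2 pool is therefore open for them.

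The fold changes of siGATA3 and siTET2 correlated with r = 0.41 across genes, those of siESR1 and siTET2 with r = 0.28, and those of siESR1 and siGATA3 with r = 0.19. Since these contrasts share the siNT libraries, 20 simulations of unchanged groups gave r of 0.50 with 0 shared calls, so that r alone says little. The covariances, which shared controls raise by the same amount with or without effects, were 0.0341, 0.0391 and 0.0511 against 0.0063, 0.0062 and 0.0062 in the simulations, leaving 0.0279, 0.0329 and 0.0449. With the siNT libraries split into 3 and 3 so that no control was shared, the same-direction overlaps were 1893, 1784 and 3826 genes in the median of 20 splits. The medians by direction were 745, 683 and 1503 genes that rose in both, where independent lists would give 269.2, 386.3 and 949.5, and 1164, 1090 and 2314 that fell in both, where they would give 505.4, 785.7 and 1795. Splitting the libraries takes out their shared noise but not an effect of the siNT pool, which remains the reference on both sides.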

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

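Of 88 group values tested for a library far from the other 5 of its group, 3 stood apart, where chance at 1 in 20 would give 4.4. PSKH1 was at 30.9 RPKM in siTET2 replicate 6, above the next library at 29.01 RPKM, a gap of 0.666 of the group's range. AGR3 was at 0.240 RPKM in siESR1 replicate 2, above the next library at 0.159 RPKM, a gap of 0.706 of the range. S100A9 was at 52.2 RPKM in siESR1 replicate 4, above the next library at 45.7 RPKM, a gap of 0.628 of the range.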

How the results depend on the processing

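Of the values that answer a comparison, 465 alternatives left the direction and the side of the threshold, or the count within 1.5 times, as reported, and 29 did not. The fits of 3 title runs, of protein-coding genes and without heptamer carriers, and the split of the siNT libraries into 2, 2 and 2, were chosen after seeing the data. For the causes of the changes below, only those that follow from fewer genes or libraries are known, and otherwise the cause was not tested. The 2-fold counts moved to 783 genes (siGATA3), 82 (siTET2) and 581 (siTET2 versus siGATA3) with a pseudocount of 0.1, and siTET2 to 16 with a pseudocount of 1, 20 among protein-coding genes and 14 without heptamer carriers, which left 3174 siTET2 genes past the threshold. Fits of 3 libraries per group gave 2504 and 2513 genes for siTET2. At 2-fold in both knockdowns, 131 (siESR1 and siGATA3), 10 (siESR1 and siTET2) and 7 genes (siGATA3 and siTET2) were shared. In all 3 knockdowns 263 genes rose and 451.5 fell with siNT split into 2, 2 and 2. With siNT split into 3 and 3, 1784 and 1893 genes were shared between siTET2 and siESR1 or siGATA3, and r was 0.162 for siESR1 and siGATA3, 0.206 for siESR1 and siTET2 and 0.305 for siGATA3 and siTET2 (Spearman 0.165, 0.194 and 0.349). With all siNT libraries shared, the Spearman values were 0.206, 0.261 and 0.462. An estimated correlation kept 2 list calls for siESR1, 0 for siGATA3 and 2 for siTET2, whereas fry, which does not compare a list with other genes, called 16 and 14 for siESR1 and siGATA3. The mitochondrially encoded list of siTET2 turned to a median of -0.039 with quantile normalization and 0.0041 with the label block, and MT-ND5 in siGATA3 to -0.047 with quantile normalization. Among single genes and lists, 91 further values no longer passed. Leaving out 1 library at a time gave 12750 to 12894 genes for siESR1, 8853 to 9155 for siGATA3 and 4376 to 4725 for siTET2. Quantile normalization moved the median log2 fold change of all genes in siESR1 from -0.09 to 0.019, so changes of that size have no firm direction there.

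The numbers in the labels did not pair the libraries: with the label number as a replicate block 5954 genes passed for siGATA3 and 1656 for siTET2, which share only number 1 with siNT, and libraries of equal number in different title runs and groups had a mean residual correlation of -0.0212. siESR1 libraries carry the same numbers as siNT libraries, and siTET2 libraries the same as siGATA3 libraries. Residuals are taken after group means are removed, so they cannot show a difference between numbers that follows the groups. If the numbers mark a shared condition, it cannot be told apart from the siGATA3 and siTET2 knockdowns outside number 1. Libraries of 1 title run had a mean residual correlation of 0.0742 (11 of 36 pairs above 0.1), and 13 of 24 libraries correlated best with their own run. With the title run as a block 5670 genes passed for siTET2, and 6 lists were called for siESR1 in place of 8, the BCL2 family and cholesterol synthesis both being at an adjusted p of 0.0527.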

Other observations

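Markers of luminal identity showed no common direction by camera in any knockdown. In siESR1 libraries 9 of 20 rose and 10 fell, with a median of -0.08 and a mean of 0.03 (camera adjusted p = 0.618). The keratin gene KRT18 rose by 1.22 and the secreted protein gene AGR2 fell by 2.86. In siGATA3 libraries 11 rose and 6 fell (camera adjusted p = 0.269), KRT18 falling by 0.83 and AGR2 by 1.16. In siTET2 libraries 4 rose, 3 fell and 13 did not pass, with 5 and 3 adjusted over the list alone (camera adjusted p = 0.357). ERBB3, a receptor tyrosine kinase gene, fell by 0.91. Basal and mesenchymal markers rose in 8 and fell in 8 of 18 cases in siESR1 libraries (median -0.14, mean 0.12, camera adjusted p = 0.661, and a median of 0.20 in the 13 without a siESR1 heptamer), rose in 7 and fell in 4 in siGATA3 (camera adjusted p = 0.0715), and rose in 4 and fell in 2 in siTET2 (camera adjusted p = 0.524). Growth factor receptors and ligands rose in 5 and fell in 9 of 16 cases in siESR1 (median -1.06, camera adjusted p = 0.342, but 0.0285 with no filter on low values and 0.0496 at a mean of at least 2 RPKM; the 7 without a siESR1 heptamer had a median of 1.00, 5 rising and 2 falling), 7 and 4 (9 and 4 adjusted over the list alone) in siGATA3 (median 0.18, mean -0.08, camera adjusted p = 0.519) and 3 and 1 in siTET2 (camera adjusted p = 0.23). Of 22 stromal, endothelial and immune markers 3 were expressed enough to test, and the list did not pass in any knockdown (camera adjusted p = 0.7, 0.235 and 0.735 for siESR1, siGATA3 and siTET2). Fry, which does not compare a list with other genes, called luminal markers upward in siESR1 (adjusted p = 3.4e-05) and basal markers upward in siGATA3 (3.64e-08). It called growth factor receptors and ligands downward in siESR1 (6.64e-11), and stromal markers downward in siESR1 and siGATA3 (1.31e-06 and 9.87e-08).

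Stress and metabolic lists that have not been described above did not pass in camera as fitted for the report. With no filter on low values the unfolded protein response and oxidative phosphorylation lists passed in siTET2 (camera adjusted p = 0.00543 and 0.0084). By fry, which does not compare a list with other genes, interferon genes and ER cofactors passed in siESR1 (adjusted p = 2.29e-05 and 3.58e-06) and the unfolded protein response in siESR1, siGATA3 and siTET2 (0.00538, 0.00108 and 0.00122). Of 19 interferon genes 7 rose and 8 fell in siESR1, 7 rose and 3 fell in siGATA3, and 1 fell in siTET2 (camera adjusted p = 0.919, 0.325 and 0.651). Unfolded protein response genes rose in 9 and fell in 10 of 22 cases in siESR1, 7 and 8 in siGATA3, and 3 and 10 in siTET2 (camera adjusted p = 0.58, 0.606 and 0.092). Adjusted over the list alone these were 10 and 10, 7 and 9, and 4 and 10. ER cofactors rose in 6 and fell in 11 of 23 cases in siESR1, 6 and 7 in siGATA3, and 2 and 5 in siTET2 (camera adjusted p = 0.618, 0.85 and 0.651). Oxidative phosphorylation genes rose in 12 and fell in 8 of 28 cases in siESR1, 8 and 7 in siGATA3, and 1 and 6 in siTET2 (camera adjusted p = 0.474, 0.92 and 0.139; in siTET2 1 and 7 adjusted over the list alone). Of the lists called elsewhere, p53 targets (8 rose and 3 fell of 22), the BCL2 family (4 and 2 of 9), YAP/TEAD targets (6 and 5 of 18), mitochondrially encoded genes (4 and 0 of 13) and ribosomal proteins (4 and 7 of 30) did not pass in siGATA3 (camera adjusted p = 0.235, 0.325, 0.325, 0.105 and 0.813). Adjusted over the list alone, 3 mitochondrially encoded genes rose, and 4 ribosomal protein genes rose and 6 fell. In siTET2, p53 targets (4 and 3), the BCL2 family (2 and 3), hypoxia genes (1 and 5 of 25) and NF-kB targets (1 and 0 of 10) did not (camera adjusted p = 0.225, 0.654, 0.651 and 0.23). Adjusted over the list alone, 2 BCL2 family genes rose and 4 fell, and 0 NF-kB targets rose. In siESR1, methylation machinery (9 and 5 of 19), hypoxia genes (8 and 11), YAP/TEAD targets (9 and 6) and mitochondrially encoded genes (4 and 6) did not (camera adjusted p = 0.342, 0.866, 0.107 and 0.783), although YAP/TEAD targets passed with no filter on low values (0.0285). Fry called methylation machinery and YAP/TEAD targets in siESR1 (adjusted p = 0.0224 and 1.53e-10). In siGATA3 it called the BCL2 family, YAP/TEAD targets and ribosomal proteins (0.00599, 0.00843 and 0.0324).

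The tests that follow were chosen before the results they measure were seen, with some exceptions. Chosen afterwards were those of scaling, of GC content and length, of a siESR1 seed in TET2, of the loss of TET2 alone and of the siGATA3 heptamers in mitosis and replication genes. No choice beforehand was recorded for the heptamer shares in siESR1 and siGATA3 libraries or for the genes of matched 3′ UTR length. TET2 RNA was lower in siESR1 than in siTET2 libraries. Scaling was argued against, since the log2 difference under 3 scalings was 0.405 at the lowest (standard error 0.089), and so were reads of the antisense gene TET2-AS1, whose span holds 0 exonic bases of TET2 and whose difference was -0.0434% of that of TET2. A siRNA seed of the siESR1 pool could not be excluded: TET2 carries TCCTACT in its 3′ UTR, and 2.25% of genes with this heptamer fell as much in siESR1, against 0.879% without it. That ESR1 loss lowers TET2 transcription remains open and untested.

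The 16 protein-coding genes other than TET2 that fell at least 2-fold in siTET2 libraries all carried one of 4 heptamers, against 33.9% of other genes (one-sided Fisher's exact test, p = 3.15e-08), where 6.28 would be given by genes of matched 3′ UTR length (p = 0.0001, the smallest that 10000 draws can give). The strongest, GAGGGTA, had a z of -13.86 against -4.90 at the lowest in 100 permutations, and 1.16 and -0.28 in siESR1 and siGATA3. Of the 4, 3 lay beyond the permutations, but GAGGGTA and GAGGGTT among them differ only in the last base. A candidate explanation is that siRNAs of the TET2 pool act on these genes through their seeds, which the siRNA sequences would settle. The median of these genes was -0.389 in siESR1 libraries (bootstrap 95% interval -0.671 to 0.051, 10 fell and 4 rose), where TET2 fell further. In siGATA3 libraries it was -0.157 (-0.369 to -0.029, 8 fell and 3 rose). Loss of TET2 alone was taken to need -0.803 and -0.459, a fixed share of the siTET2 median scaled by the fall of TET2. Both medians fell short of that. This argues against loss of TET2 alone only if falls scale with that of TET2 and the other knockdowns do not otherwise move these genes. The genes were also picked for their falls in siTET2 libraries. A role of TET2 at single genes among the 16 remains open. In siESR1 libraries 526 of the 1005 genes that fell at least 2-fold carried one of its 4 heptamers (one-sided Fisher's exact test, p = 3.17e-35, odds ratio 2.28), where 362.8 would be given by genes of matched 3′ UTR length (p = 0.0001). All 4 lay beyond the permutations, but CCCTACT, ACCTACT and TCCTACT differ only in the first base. Seeds stay open for part of these falls too. In siGATA3 libraries 84 of 211 such genes carried one of their 4 heptamers, 39.8% against 34.8% of the rest (one-sided Fisher's exact test, p = 0.0747, 95% interval of the odds ratio 0.928 to 1.65), where 71.9 would be given by genes of matched 3′ UTR length (p = 0.03). Of these heptamers 1, GACCAGA, had a z of -10.48 against -4.51 at the lowest in permutations. The others, at -4.14, -4.03 and -3.71, did not lie beyond the permutations. GACCAGA alone was in 38 of the 211 genes and in 1205 of the 11707 others, a difference that was not tested. Seeds stay open for some of these falls as well.

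Mitosis and replication genes were lower in siTET2 and siGATA3 libraries. Correction for GC content and length left at least 0.920 of each list median, scaling at least 0.904, and leaving out carriers of the heptamers at least 0.860 in siTET2 and 0.971 in siGATA3, all of which argue against these as the whole cause. A smaller share of cycling cells may follow from either knockdown, as a hypothesis that these data do not test. An effect of siRNA seeds on an upstream regulator of the cell cycle also stays open.

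Other splits of the 12 libraries of each contrast were set beside each count, 100 of the 462 possible ones. For siESR1 1 split, the real one, reached 13075 genes (highest other 9889), and likewise 1 for siGATA3 (9229, highest other 6019), siTET2 (4892, 1208), siTET2 versus siESR1 (12898, 9767), siTET2 versus siGATA3 (8294, 4945) and siGATA3 versus siESR1 (13030, 9868). These counts therefore argue against a chance assignment of these libraries to the groups. They do not exclude it, since the remaining splits were not run and the splits did not keep to the title runs. Chance differences between cultures cannot be judged in this way, since the labels do not say that the libraries of a group came from separate cultures. For the number of lists called, 3 splits reached the 8 of siESR1 (highest other 8, median of the others 5), a share under 0.05. That count was 6 with the title run as a block and lower with an estimated correlation. The splits were not run under those settings, so chance is argued against only for the unblocked count at the preset correlation. Chance cannot be excluded for the 7 lists of siGATA3, which 40 splits reached (highest other 11, median 6), or the 9 of siTET2, which 9 splits reached (highest other 10, median 4).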
